A study of Mus musculus with 8 samples.

How the data were processed

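RNA was measured in 8 libraries of peripheral blood leukocytes from male wild-type C57BL/6 mice. The labels state that 1e+06 cells per condition were lysed, that total RNA was extracted by the mirVana protocol, and that strand-specific paired-end TruSeq libraries were sequenced on a NextSeq-550. Whether each library came from 1 mouse or from a pool was not stated.

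The values used are fragments per kilobase of transcript per 1e+06 mapped fragments (FPKM), as deposited by the authors in a single table with 1 value per gene and library. The submitters' processing notes name TopHat 1.20, Cufflinks, Cuffdiff and the build mm9, without their settings. Gene positions in the table were compared with 2 mouse annotations. Of 21249 genes matched by symbol to a GRCm38 table, 99.5% overlapped their GRCm38 position, whereas 11.4% of 20941 genes overlapped their NCBI37 (mm9) position. Coordinates are therefore given as in the table and read as GRCm38, although the notes name mm9. FPKM scales each library by its own total and each gene by its length, so a transcript class that takes a larger share of a library lowers the FPKM of every other gene in it.

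The table held 23847 entries, of which 23527 had a number in all 8 libraries. Another 312 entries were marked LOWDATA, 7 HIDATA and 1 FAIL in place of a number and were left out. The HIDATA entries were alpha and beta globin genes, so haemoglobin transcripts have no value, and whether their fragments count in the denominator of the other genes is unknown. A value of 0.001 was the lowest in every library and was read as no fragments. In 519 entries the symbol occurred more than once, and 23200 distinct symbols remained. Another 25 symbols had been turned into dates, as spreadsheet programs do, and were used as they stand.

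Genes with at least 1 FPKM in at least 2 libraries were tested, 9523 in all, as log2(FPKM + 1). A linear model with 4 group means was fitted to the 8 libraries with limma 3.58.1 in R 4.3.3, with a moderated test whose prior variance followed the mean level (trend). The residual degrees of freedom were 4 and the prior degrees of freedom 7.38. Tests were two-sided and adjusted by Benjamini-Hochberg over all genes within each comparison, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) of this fit. Tools for counts were not used, because the values are not counts. The comparisons were infection in normoxia, infection after hypoxia, hypoxia without infection, hypoxia in infected mice, the difference between the 2 infection effects, and the mean infection and mean hypoxia effects over the other factor.

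Lists of genes for pathways and cell types, 29 in all, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all in limma, and adjusted over the lists within each comparison. Camera compares a list with the other genes, whereas fry tests whether its genes move one way on balance. For the 4 comparisons of 2 groups and for the difference of infection effects, named genes were the 10 largest rises and the 10 largest falls past the threshold. A mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries were also required, the latter not for the difference of effects. Gene models, microRNAs and other small RNAs, pseudogenes, and immunoglobulin and T cell receptor segments were excluded. Where fewer than 10 passed, the smallest unadjusted p filled the list, and these genes are described as not passing. Some genes that the rule named are not reported here. Each described list gives up to 4 members, those past the threshold with the largest change first and then those with the highest mean FPKM. Hif1a, Slc2a1, Pfkfb3, Ldha, Il1b, Tnf and Il10 are given whatever their values. Genes named for the mean effects over the other factor were chosen after their values were seen, because the rule did not cover these comparisons. Lists for haem synthesis, the ATF4 programme, glucocorticoid-induced genes and clock genes were written after the main results were seen. Their list tests were adjusted over these later lists alone, apart from the 29.

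Counts of fragments per library were not used here, so the depth is unknown and no counting interval is given. A relative depth was estimated from genes seen in at most 4 libraries, whose low values step by whole fragments. Ratios to naive control 2 were called whole when within 0.03 log2 of a ratio of whole numbers up to 5. Between 82.2% and 91.5% of ratios met this, against 20.1% to 23.0% with a displaced step.

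The pipeline was tested on simulated data with the spread of the real fit, 200 changed genes and 5 simulations per comparison. For infection in normoxia it called 41.2% of genes changed by 1 log2 and 99.4% of those changed by 2, and for the difference of infection effects 9.85% and 86.0%. All 3 list tests called the shifted list in 5 of 5 simulations and no other list. Errors were simulated independently for each gene and with the same spread in all groups. The shares are therefore not the power of the real design, and the list result does not cover genes that are correlated.

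Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, quantile normalization, scaling to a common upper quartile, a term for the replicate number, a robust prior, the libraries of each comparison alone, and leaving out each library in turn. The exclusion of small RNA genes, and the exclusion of naive infected 1 together with preconditioned control 2, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.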

Results

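Transcript levels were measured in peripheral blood leukocytes of mice kept in normal air (naive) or preconditioned by exposure to 10% oxygen (hypoxia), each with or without a bacterial infection. The 4 groups of naive control, naive infected, preconditioned control and preconditioned infected mice held 2 libraries each. The labels give neither the bacterium nor the length of the exposure. Between 7856 and 9601 genes reached 1 FPKM in a library. Relative to naive control 2, the estimated depth was 1.21 and 0.916 in naive infected, 0.799 in naive control 1, 0.793 and 0.560 in preconditioned infected, and 0.504 and 0.425 in preconditioned control libraries. The 3 lowest were hypoxia libraries, while preconditioned infected 1 and naive control 1 did not differ by more than the 0.03 log2 tolerance of the method. Genes of small RNAs took between 21.3% and 38.4% of the summed FPKM.

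Marker genes of blood cells separated the groups. Platelet markers were lower in all 4 hypoxia libraries, where their mean level was 6.11 to 6.31 on the log2 scale, than in the 4 naive libraries, where it was 7.54 to 7.74. Mature neutrophil markers had a mean level of 5.92 to 6.63 in infected and 4.18 to 5.41 in uninfected libraries. Erythroid markers ranged from 4.17 in naive infected 1 to 6.26 in preconditioned control 1. The first 4 principal components held 40.9%, 26.5%, 13% and 6.57% of the variance. Replicates differed by over 2-fold for 66 genes in naive controls, 587 in naive infected, 442 in preconditioned controls and 86 in preconditioned infected mice. Naive infected 1 had higher levels of T cell markers, 3.54 against 2.34, and of ribosomal protein genes, 7.38 against 6.90, than naive infected 2. Preconditioned control 2 had higher B cell markers, 4.19 against 2.78, and lower neutrophil markers, 4.18 against 5.41, than preconditioned control 1.

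**Figure D1:**
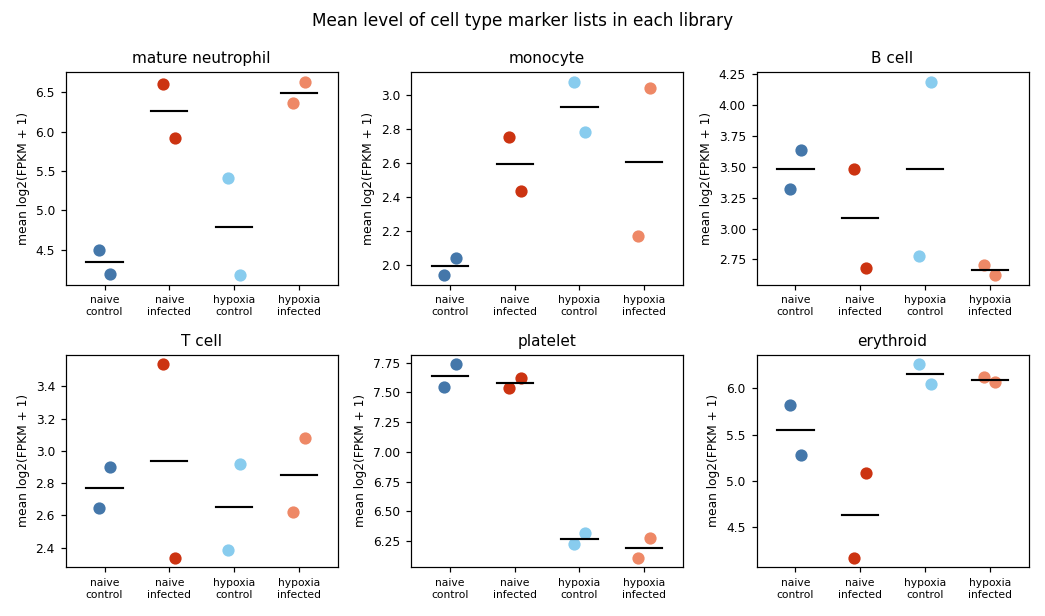
Mean log2(FPKM + 1) of 6 cell type marker lists, with 1 point per library (2 per group, 8 in all) and a bar at each group mean; the vertical axes differ in range and do not start at 0. Platelet markers lie between 6.11 and 6.31 in hypoxia libraries and between 7.54 and 7.74 in naive libraries, and neutrophil markers are higher in the infected groups.

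Infection in normoxia was compared to ask how leukocytes of naive mice responded to bacteria. Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715676), rose from 3.69 ± 1.75 to 34.8 ± 0.821 FPKM (SD, n = 2 per group), a log2 change of 2.98 ± 0.44. Ltf, the iron-binding lactoferrin of neutrophil granules (chromosome 9, 111019292 to 111042766), rose from 2.87 ± 0.674 to 26.0 ± 8.49 FPKM, a log2 change of 2.78 ± 0.33. The largest change was that of Ifitm6, a member of the interferon-induced transmembrane family, at 3.27 ± 0.46, followed by the neutrophil surface protein Cd177 at 3.04 ± 0.45. Chi3l3, a chitinase-like secreted protein, rose by 2.91 ± 0.42 and Clec5a, a myeloid lectin receptor, by 2.27 ± 0.34.

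The other genes that passed were Flot2 at 2.16 ± 0.34, the calcium-binding S100a6 at 2.16 ± 0.31, Alas1, the housekeeping enzyme that starts haem synthesis, at 1.97 ± 0.32, and Glrx, a glutaredoxin, at 1.93 ± 0.28. Beyond the 10 largest rises, Ly6c2 (1.93 ± 0.30), the short-chain fatty acid receptor Ffar2 (1.78 ± 0.28), Adamtsl4 (1.75 ± 0.26) and Fdxr (1.53 ± 0.24) also passed and complete the 14. No fall passed. Those with the smallest unadjusted p were Gvin1 (-1.43), the erythrocyte skeleton genes Ank1 (-1.41), Epb4.2 (-1.43) and Tmod1 (-1.24), Mgst3 (-1.21), Apol11b (-1.27), Apol11a (-1.03), Cmas (-1.21), Car2 (-1.49) and Isg15 (-1.29), with adjusted p from 0.0591 to 0.0896.

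Among the fixed genes, Il1b, which encodes the cytokine interleukin 1 beta, had a log2 change of 2.10 (adjusted p = 0.0713). The glucose transporter gene Slc2a1 had 1.51 (0.0551) and Ldha, which encodes a lactate dehydrogenase subunit, 1.11 (0.0665). Hif1a, the oxygen-regulated transcription factor, had 1.02 (0.0910), the cytokine gene Tnf 0.80 (0.0722) and the glycolytic regulator Pfkfb3 0.78 (0.194). None of these passed. Il10 stayed below the filter, with a highest value of 0.341 FPKM, in naive infected 2.

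Of 21 mature neutrophil markers, 1 rose (Cd177) and 21 did when adjusted over the list alone, with a median log2 change of 1.88. S100a9 and S100a8, the subunits of calprotectin, had 2.73 ± 0.50 and 2.63 ± 0.47, and Retnlg had 2.39 ± 0.46, none past the threshold over all genes. Of 9 granule and immature neutrophil genes 3 rose (Cd177, Chi3l3 and Ltf; 9 adjusted over the list alone), and of 19 NADPH oxidase and antimicrobial genes 2 did (Chi3l3 and Ltf; 16). These 3 lists share members, and the primary granule genes Mpo, Elane, Prtn3 and Ctsg lay below the filter and were not tested. Camera's adjusted p was 1.83e-22, 8.83e-13 and 9.39e-17 in that order, and the adjusted p = 0.246 with an estimated correlation in each. None of 28 pattern recognition genes passed, while 15 did when adjusted over the list alone (camera adjusted p = 1.01e-07; adjusted p = 0.541 with an estimated correlation), with Clec7a, a receptor for fungal glucans, at 1.68 and the endotoxin co-receptor Cd14 at 2.13. None of 18 erythroid markers passed and 8 fell when adjusted over the list alone, with a median of -1.01 (camera adjusted p = 1.96e-20; adjusted p = 0.246 with an estimated correlation). This median was -0.31 without naive infected 1, whose erythroid level was 4.17 against 5.08 in naive infected 2, and -1.56 without naive infected 2.

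In all, limma called 14 of 9523 genes, all higher, with adjusted p from 0.0327 to 0.0396, and 1328 genes had an unadjusted p under 0.05. The median change of all genes was 0.14, which fell to -0.06 after quantile normalization and to -0.10 with upper quartile scaling. Both left 0 genes past the threshold in limma, with 1488 and 1424 at an unadjusted p under 0.05. The count was 0 without naive infected 1 (879 unadjusted), 1193 without naive infected 2, 111 without naive control 1, 1 without naive control 2 and 486 without either preconditioned control. Leaving out small RNA genes gave 372, and leaving out naive infected 1 and preconditioned control 2 together gave 516.

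Infection after hypoxia asked the same question in preconditioned mice. Saa3 rose again, from 2.12 ± 1.88 to 55.9 ± 25 FPKM, a log2 change of 4.26 ± 0.44. Lipg, which encodes an endothelial lipase (chromosome 18, 74939322 to 74961263), rose by 3.96 ± 0.49, from 1.39 ± 1.94 to 29.4 ± 1.81 FPKM. Ifitm6 rose by 3.04 ± 0.46, Flot2 by 2.36 ± 0.34 and Ggt1, a gamma-glutamyltransferase, by 2.16 ± 0.31. The remaining 2 calls lay outside the rule for named genes and were chosen after their values were seen: Gm766 rose by 1.28 ± 0.19 and the microRNA gene Mir1949 fell by 8.73 ± 0.23, a fitted value that depends on the pseudocount, since infected libraries were at the lowest value.

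Rises that did not pass were Stfa1 at 1.80, Rdh12 at 2.05, Klhdc4 at 2.11, the tetraspanin Cd63 at 1.82 and the decoy interleukin 1 receptor Il1r2 at 3.43, with adjusted p from 0.0698 to 0.0835. Falls that did not pass were Ifi30 (-1.16), Rnase6 (-1.19), the cytotoxic granule gene Gzma (-1.36), Snrnp25 (-0.69), Fbxo9 (-0.71), the transcription factor Irf8 (-0.89), Lst1 (-0.60), the class II antigen-presentation gene H2-Ab1 (-1.27), Pld4 (-1.10) and Ahnak (-0.90), with adjusted p from 0.188 to 0.339. Of the fixed genes, Slc2a1 had 1.5 and Pfkfb3 1.34 (adjusted p = 0.105 for both), Il1b 1.57 (0.252), Ldha 0.94 (0.187), Hif1a 0.70 (0.367) and Tnf 0.17 (0.910).

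Mature neutrophil markers had a median log2 change of 1.71, which was 2.29 without preconditioned control 1 and 1.13 without preconditioned control 2. None of the 21 passed and 18 did when adjusted over the list alone (camera adjusted p = 1.37e-20; adjusted p = 0.374 with an estimated correlation). S100a8 had 2.02 ± 0.47, S100a9 1.99 ± 0.50, Retnlg 2.01 ± 0.46 and the collagenase gene Mmp8 2.75 ± 0.77. All 20 B cell markers had negative changes, with a median of -0.84, and none passed over all genes or over the list alone (camera adjusted p = 5.19e-17; adjusted p = 0.374 with an estimated correlation). Cd79a and Cd79b, the signalling chains of the B cell receptor, had -1.04 and -0.74. This list followed preconditioned control 2, whose B cell level of 4.19 was the highest of the 8 libraries: the median was -0.11 without it and -1.55 without preconditioned control 1. Limma called 7 of 9523 genes, 6 higher and 1 lower, and 1020 had an unadjusted p under 0.05. The count was 3 without preconditioned infected 2, 454 without preconditioned control 1, 71 without either naive control and 15 without either naive infected library. It was 3 under both scalings, 94 without small RNA genes and 171 without naive infected 1 and preconditioned control 2. Of the 14 rises in normoxia and the 6 after hypoxia, 3 were shared, against 0.00882 for independent lists, and log2 changes correlated across genes with r = 0.51, where genes are not independent replicates. Both comparisons used the same estimate of spread for each gene, so the 2 lists of rises are not independent.

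Averaged over both oxygen arms, with 4 infected against 4 uninfected libraries, the infection response called many more genes. All 21 mature neutrophil markers rose, with a median of 1.82 that stayed between 1.38 and 2.14 over all settings tried. The counts of rises in this list and those below hold for the main fit. Without the filter on low values 0 of all genes rose, and after quantile normalization 24 did. Examples were Il1r2 (2.81 ± 0.42), Mmp8 (2.72 ± 0.55), Cd177 (2.53 ± 0.32) and S100a9 (2.36 ± 0.35). Of 19 NADPH oxidase and antimicrobial genes 14 rose (16 adjusted over the list alone), among them Ngp (2.85 ± 0.38) and the iron-scavenging lipocalin gene Lcn2 (2.21 ± 0.38). Of 28 pattern recognition genes 13 rose (16), among them Cd14 (2.24 ± 0.39) and the amplifying myeloid receptor gene Trem1 (1.77 ± 0.27). Of 13 pro-inflammatory cytokine genes 6 rose (10), among them Il1b (1.83 ± 0.38) and the chemokine gene Cxcl2 (1.74 ± 0.47). Of 16 anti-inflammatory regulators 10 rose (11), among them the resolvin and annexin receptor gene Fpr2 (2.34 ± 0.37) and Anxa1 (2.28 ± 0.36).

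Of 18 genes for glycolysis and glucose uptake 9 rose (11 adjusted over the list alone), among them the lactate exporter gene Slc16a3 (1.69 ± 0.28), Slc2a1 (1.51 ± 0.22) and Pfkfb4 (1.28 ± 0.23). Pfkfb3 (1.06 ± 0.19), Ldha (1.03 ± 0.19) and Hif1a (0.86 ± 0.20) passed too, while Tnf did not (0.49, adjusted p = 0.0655). Camera's adjusted p was 6.17e-22 for the mature neutrophil list and 2.86e-07 for glycolysis. No infection list kept its call with an estimated correlation: the adjusted p = 0.366 with an estimated correlation for mature neutrophils and for anti-inflammatory regulators, 0.381 for glycolysis, 0.399 for pattern recognition and 0.318 for cytokines, and fry's adjusted p was 0.0515 for mature neutrophils. In all, 728 genes rose and 5 fell (Mir1949, Gvin1, Epb4.2, Ank1 and Fbxo9), with 1900 at an unadjusted p under 0.05. The count was 320 without naive infected 1, 2348 without naive infected 2, 390 without naive control 2, 261 without preconditioned infected 2 and 430 without preconditioned control 2. It was 26 after quantile normalization and 55 with upper quartile scaling, under which the median of all genes went from 0.12 to -0.06 and -0.11. Without the filter on low values it was 1, a fall, so the list counts of rises above hold for the main fit.

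Hypoxia without infection asked what preconditioning alone changed. Ccr2, the chemokine receptor of inflammatory monocytes (chromosome 9, 124102183 to 124109140), rose from 0.628 ± 0.338 to 28.9 ± 13.1 FPKM, a log2 change of 4.14 ± 0.69. Ppbp, a platelet chemokine gene (chromosome 5, 90768518 to 90770060), fell from 2981 ± 385 to 1019 ± 245 FPKM. Asns, the asparagine synthetase gene (chromosome 6, 7675171 to 7693182), rose from 1.38 ± 0.207 to 9.47 ± 0.281 FPKM, a log2 change of 2.14 ± 0.24. Fkbp5, a glucocorticoid-induced co-chaperone gene, fell from 17 ± 3.65 to 2.56 ± 0.760 FPKM, a log2 change of -2.34 ± 0.37.

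The remaining largest rises were Chi3l3 (3.43 ± 0.42), the fibronectin gene Fn1 (2.99 ± 0.63), S100a4 (2.44 ± 0.55), the metalloreductase gene Steap4 (2.21 ± 0.51), Clec4a3 (2.11 ± 0.46), Ms4a4c (2.11 ± 0.37), Myo1f (2.07 ± 0.34) and the perforin-like Mpeg1 (2.01 ± 0.37). The remaining largest falls were the metallothionein gene Mt1 (-2.90 ± 0.66), the inhibitory lymphocyte receptor gene Btla (-2.02 ± 0.40), the stress-induced mTOR inhibitor gene Ddit4 (-2.0 ± 0.42), Prr7 (-1.98 ± 0.26), Plxna4 (-1.92 ± 0.29), Sdpr (-1.91 ± 0.25), the von Willebrand factor gene Vwf (-1.90 ± 0.31), the phosphatase gene Ptpn22 (-1.88 ± 0.35) and Draxin (-1.86 ± 0.23). Adjusted p for these 20 genes lay between 0.00786 and 0.0241. Of the fixed genes Pfkfb3 fell by 1.71 (adjusted p = 0.00803), whereas Hif1a (-0.85, 0.0880), Slc2a1 (-0.52, 0.320), Ldha (-0.38, 0.402), Il1b (0.77, 0.387) and Tnf (0.44, 0.202) did not pass.

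Of 19 platelet and megakaryocyte markers 16 fell and 19 did when adjusted over the list alone, with a median of -1.38. Tubb1, a platelet tubulin gene, fell by 1.84 ± 0.31, and the membrane glycoprotein genes Gp6, Gp5 and Itgb3 fell by 1.68 ± 0.24, by 1.64 ± 0.27 and by 1.61 ± 0.28, respectively. Camera's adjusted p was 3.14e-12, with an adjusted p = 0.659 with an estimated correlation, and fry's adjusted p was 0.00471. Of 21 monocyte and macrophage markers 11 rose and 1 fell (12 and 4 adjusted over the list alone), with a median of 1.37 (camera adjusted p = 2.83e-08; adjusted p = 0.670 with an estimated correlation); Ly6c2, a surface marker of inflammatory monocytes, rose by 1.74 ± 0.30. Mature neutrophil markers had a median of 0.62, and 3 of 21 rose, among them Slpi (1.43) and Stfa2l1 (1.42) (camera adjusted p = 1.44e-06; adjusted p = 0.755 with an estimated correlation); without preconditioned control 1 the median was 0.11 and the camera adjusted p 0.635. Of 37 interferon-stimulated genes 3 rose and 1 fell (6 and 1 adjusted over the list alone): Ifi204 (1.39), Oas1a (1.01) and Usp18 (0.94) rose and Ifit2 fell by 1.24 (camera adjusted p = 5.46e-09; adjusted p = 0.659 with an estimated correlation).

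Genes of glycolysis did not rise as a group: 1 of 18 rose (Hk3, 1.60) and 3 fell (Pfkfb3, the glucose transporter gene Slc2a3 at -1.43 and Hk1 at -1.24), 1 and 6 adjusted over the list alone (camera adjusted p = 0.204). In the unfolded protein and amino acid stress list 3 of 25 rose and 2 fell, led by Asns and Atf3 (1.21), with the endoplasmic reticulum genes Edem1 (-1.05) and Herpud1 (-1.01) falling (camera adjusted p = 0.000179; adjusted p = 0.755 with an estimated correlation). Of 18 erythroid markers 1 rose, also when adjusted over the list alone, with a median of 0.60 (camera adjusted p = 7.08e-08; adjusted p = 0.755 with an estimated correlation). Limma called 746 genes, 111 higher and 635 lower, with 2417 at an unadjusted p under 0.05. Falls made up 85.1% of calls as deposited, 59.1% after quantile normalization and 56.4% with upper quartile scaling. The median of all genes moved from -0.24 to -0.03 and -0.02 under these scalings, and counts rose to 1606 and 1307. The count was 4 without naive control 1, 12 without naive control 2, 335 without preconditioned control 1, 486 and 484 without preconditioned infected 1 or 2, 1786 and 1792 without naive infected 1 or 2, and 3064 without naive infected 1 and preconditioned control 2 together.

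Hypoxia in infected mice compared preconditioned with naive animals during infection. Most erythroid markers rose, while platelet genes and Ltf fell. Ltf fell from 26.0 ± 8.49 to 2.75 ± 0.0769 FPKM, a log2 change of -2.81 ± 0.33. Hif1a (chromosome 12, 73907867 to 73947530) fell from 22.7 ± 0.824 to 9.69 ± 2.76 FPKM, a log2 change of -1.17 ± 0.28 (adjusted p = 0.0256).

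Other large rises were Steap4 (3.07 ± 0.51), the red cell skeleton genes Add2 (2.78 ± 0.37) and Tmod1 (2.65 ± 0.34), the antioxidant genes Prdx2 (2.33 ± 0.43) and Gpx1 (2.27 ± 0.38), the mitochondrial folate enzyme gene Mthfd2 (2.21 ± 0.47), the ubiquitin-like Isg15 (2.16 ± 0.35) and Urod (2.15 ± 0.38) of haem synthesis. The other largest falls were Mt2 (-2.51 ± 0.57), Ddit4 (-1.97 ± 0.42), Plscr1 (-1.93 ± 0.47), the transcription regulator gene Id2 (-1.91 ± 0.29), Camp (-1.89 ± 0.46), which encodes the antimicrobial cathelicidin, Rsc1a1 (-1.85 ± 0.31), Mest (-1.80 ± 0.25), Nrgn (-1.78 ± 0.29) and the tetraspanin Cd9 (-1.78 ± 0.31). Adjusted p for these genes and Ltf lay between 0.00789 and 0.0266. Pfkfb3 fell by 1.16 (adjusted p = 0.0240), whereas Slc2a1 (-0.53, 0.306), Ldha (-0.55, 0.233), Il1b (0.23, 0.818) and Tnf (-0.19, 0.588) did not pass.

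All 19 platelet markers fell, also when adjusted over the list alone, with a median of -1.41 (camera adjusted p = 1.41e-12; adjusted p = 0.338 with an estimated correlation; fry adjusted p = 0.00460). Nrgn, Gp6 (-1.74 ± 0.24), Ppbp (-1.72 ± 0.35) and the ADP receptor gene P2ry12 (-1.54 ± 0.28) fell most. Of 18 erythroid markers 13 rose (16 adjusted over the list alone), with a median of 1.61, among them Tspan33 (2.12 ± 0.43) and the anion exchanger gene Slc4a1 (2.09 ± 0.40). Camera's adjusted p for this list was 2.26e-23, with an adjusted p = 0.338 with an estimated correlation. The erythroid level was lowest in naive infected 1, at 4.17, against 5.08 in naive infected 2. Of 37 interferon-stimulated genes 4 rose and 1 fell (6 and 1 adjusted over the list alone): Isg15, Oas3 (1.72) and Rsad2 (1.61) rose most and Ifit2 fell by 1.42 (camera adjusted p = 1.52e-06; adjusted p = 0.772 with an estimated correlation).

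Of 17 HIF target genes outside glycolysis 4 fell, also when adjusted over the list alone: Ddit4, Ndrg1 (-1.51), Bhlhe40 (-1.10) and Gbe1 (-0.89). The list as a whole did not pass (camera adjusted p = 0.810), and its median of -0.09 became 0.11 after quantile normalization and 0.10 with upper quartile scaling. Over all settings tried, the median of this list ran from -0.41 to 0.13. Of 18 glycolysis genes 4 fell (5 adjusted over the list alone), Slc2a3 (-1.34), Pfkfb3, Tpi1 (-1.04) and Hk1 (-0.88), with a camera adjusted p of 0.338. In the cell cycle list 3 of 22 rose and 1 fell (4 and 1 adjusted over the list alone): Nusap1 (2.01), Ube2c (1.90) and the proliferation marker Mki67 (1.45) rose and Mcm4 fell by 0.96 (camera adjusted p = 7.72e-05; adjusted p = 0.243 with an estimated correlation).

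Limma called 890 genes in infected mice, 190 higher and 700 lower, with 2366 at an unadjusted p under 0.05. Falls made up 78.7% of calls as deposited, 55.8% after quantile normalization and 49.0% with upper quartile scaling, under which the count was 541. The median of all genes was -0.27 as deposited and -0.03 under both scalings. Limma called 0 genes without preconditioned infected 1 and 0 without preconditioned infected 2, with 1198 and 1826 at an unadjusted p under 0.05. The count was 2770 without naive infected 2, 554 without naive infected 1, 537 and 538 without naive control 1 or 2, and 1680 without naive infected 1 and preconditioned control 2. The hypoxia effects with and without infection shared no library. Of 635 and 700 falls, 472 were shared, against 46.7 for independent lists, and of 111 and 190 rises, 38 were shared, against 2.21. Both comparisons used the same estimate of spread for each gene. Both also carried a downward shift of all genes (medians -0.24 and -0.27). The lists are therefore not independent, and the excess cannot be read as replication alone. Log2 changes correlated across genes with r = 0.65, where genes are not independent replicates.

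**Figure D2:**
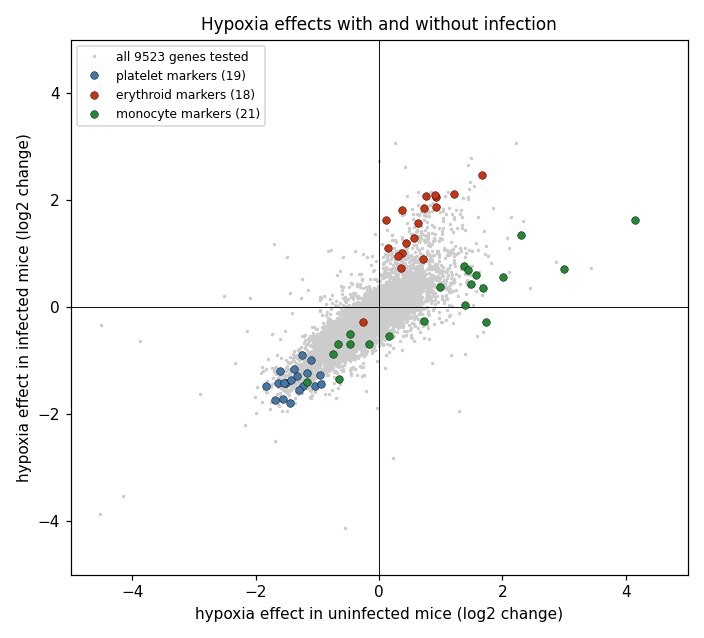
Log2 change with hypoxia in uninfected mice (horizontal) against that in infected mice (vertical) for 9523 genes, each from 2 against 2 libraries, with 3 marker lists coloured; 12 genes lie outside the drawn range of -5 to 5. The 19 platelet markers lie below 0 on both axes, most erythroid markers lie above 0 on both, and 6261 genes are negative on both, a share that includes the shift of all genes.

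Averaged over infection, with 4 libraries on each side, hypoxia lowered all 19 platelet markers, with a median of -1.40 (camera adjusted p = 2.10e-11; adjusted p = 0.490 with an estimated correlation; fry adjusted p = 0.00118). Over all settings tried, the median of this list stayed between -1.42 and -1.09. Of 18 erythroid markers 14 rose (15 adjusted over the list alone; camera adjusted p = 8.99e-16; adjusted p = 0.517 with an estimated correlation). Of 37 interferon-stimulated genes 11 rose and 2 fell (13 and 3), led by Isg15 (1.64) with Ifit2 at -1.33 in the other direction (camera adjusted p = 7.08e-09; adjusted p = 0.517 with an estimated correlation). Of 7 HIF pathway genes 4 fell (4), Hif1a by 1.01 ± 0.20, the prolyl hydroxylase gene Egln2 by 0.86 ± 0.18, Vhl by 0.61 ± 0.20 and Hif1an by 0.58 ± 0.18 (camera adjusted p = 0.261). Of 18 glycolysis genes 9 fell and 1 rose (12 and 1), with Pfkfb3 at -1.43 ± 0.19 and Slc2a3 at -1.38 ± 0.18 (camera adjusted p = 0.345).

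Of 15 class I antigen-presentation genes 4 fell (4 adjusted over the list alone), H2-Q4 (-1.45), B2m (-1.18), Tap1 (-0.80) and H2-D1 (-0.62), with a camera adjusted p of 0.610. Of 24 T cell markers 3 fell (2), Cd28 (-1.01), Tcf7 (-0.83) and Lat (-0.69), with a median of -0.01 that became 0.21 and 0.23 under the 2 scalings. Over all settings tried, this median ran from -0.43 to 0.23. In all, 456 of 9523 genes rose and 2073 fell, with 3866 at an unadjusted p under 0.05. Beside this share of falls over all genes, the falls in the class I and T cell lists do not set those lists apart. Falls made up 82.0% of calls as deposited, 56.1% after quantile normalization and 55.3% with upper quartile scaling. The count was 1438 without naive control 1, 1194 without naive control 2, 1158 without preconditioned infected 1, 1645 without preconditioned infected 2 and 4666 without naive infected 2.

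Whether preconditioning changed the response to infection was tested as the difference between the infection effects after hypoxia and in normoxia. A single gene passed in limma, the microRNA gene Mir1949 (chromosome 18, 35554567 to 35554636), which lay outside the rule for named genes and was chosen after its values were seen. It was at 390 and 463 FPKM in preconditioned controls and at the lowest value of 0.001 in the other 6 libraries. These values stood in nearly the same ratio as the worth of a single fragment in the 2 libraries, 1.99 and 2.35 relative to naive control 2. The same number of fragments in each, which may be small, would give this. Preconditioned controls also had the lowest estimated depth, 0.504 and 0.425. Ltf came next, with a difference of -3.04 ± 0.47 (adjusted p = 0.191): it rose with infection in normoxia and had -0.26 after hypoxia. The other negative differences with the smallest unadjusted p were Ly6c2 (-2.02), Chi3l3 (-2.70), Fdxr (-1.36), Plbd1 (-1.45), the complement gene C3 (-1.48), Plac8 (-1.40), Ifi30 (-1.42), Marcksl1 (-1.02) and Camp (-1.86). The positive ones were Apol11a (1.24), Apol11b (1.44), Pink1 (1.45), Mgst3 (1.19), Urod (1.52), Ppp1r15a (1.12), Car2 (1.53), Tmem38b (1.79) and Cpne8 (0.90). All of these but Ltf had an adjusted p of 1.00, as did Hif1a (-0.32), Slc2a1 (-0.02), Pfkfb3 (0.55), Ldha (-0.17), Il1b (-0.54) and Tnf (-0.63).

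The median difference was -0.03 over all genes, and 132 genes had an unadjusted p under 0.05. Leaving out small RNA genes removed Mir1949 and left 0 calls in limma, with 139 at an unadjusted p under 0.05. The count was 10 without preconditioned control 2, 9 without preconditioned control 1, 3 without naive control 1 or preconditioned infected 2, 2 without naive infected 1, and 25 without naive infected 1 and preconditioned control 2. In simulated data of this size, 9.85% of differences of 1 log2 and 86.0% of differences of 2 log2 were called. These simulations had errors independent between genes and the same spread in every group, so the shares are not the power of this comparison. They called 100% of differences of 3 log2, whereas Ltf did not pass in the real data at -3.04.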

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

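The tests of the differences below were chosen before the data were examined, and Mir1949 was singled out after its values were seen. Each item met a test of the difference between the infection effect after hypoxia and that in normoxia, adjusted over all genes or, for gene lists, over the 29 lists with camera at its preset correlation. The difference for Mir1949 was -8.73 log2, a fitted value that depends on the pseudocount, with 390 and 463 FPKM in preconditioned controls and the lowest value of 0.001 in the other 6 libraries. It is 1 of the small RNA genes, which took 21.3% to 38.4% of the summed FPKM. Its values in the preconditioned controls may rest on the same small number of fragments.

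Gene lists are given as the median log2 difference. Monocyte and macrophage markers had -0.74 (camera adjusted p = 1.72e-18), NK cell and cytotoxic markers -0.86 (9.14e-11) and NADPH oxidase and antimicrobial effectors -0.69 (9.14e-11). Granule and immature neutrophil genes, of which no primary granule gene passed the filter, had -0.32 (6.93e-08), heat shock and immediate early genes -0.34 (2.04e-05) and MHC class II genes -0.68 (0.000251). B cell markers had -0.41 (0.0016), pro-inflammatory cytokines and chemokines -0.37 (0.0172), oxidative phosphorylation subunits -0.16 (0.0156) and the unfolded protein and amino acid stress list -0.21 (0.0461). Erythroid markers had 0.92 (1.72e-18) and cell cycle genes 0.19 (0.00262). No list passed with an estimated correlation, where the smallest adjusted p was 0.350, or with fry, where it was 0.996. Only the monocyte, NK cell, NADPH oxidase and heat shock lists kept their call with each library left out in turn.

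Over all settings tried, the medians were -1.37 to -0.46 for monocyte, -1.16 to -0.22 for NADPH oxidase and -0.58 to -0.097 for heat shock genes. NK cell markers had -1.39 to -0.0074, the upper end without naive infected 1 and preconditioned control 2 together, where the call was lost. Granule and immature neutrophil genes had -1.40 to 0.12, with a median of 0.12 without naive infected 1, and lost their call without preconditioned control 1. Oxidative phosphorylation subunits had -0.35 to 0.13 and lost their call without naive infected 2, naive control 1, preconditioned infected 1 or preconditioned control 2. The unfolded protein list had -0.40 to 0.0097 and lost its call without naive infected 2, naive control 2, preconditioned infected 1 or preconditioned control 1. Cytokines had -0.57 to -0.050 and lost their call without naive control 2 or preconditioned control 1, and camera's direction turned without naive infected 2. B cell markers had -1.11 to 0.76 and MHC class II genes -1.35 to 0.52; without preconditioned control 2 their medians turned to 0.34 and 0.23, and both lost their call without naive infected 2, B cell markers also without preconditioned infected 2. Cell cycle genes had 0.044 to 0.34, lost their call without preconditioned infected 1 and turned in camera without naive infected 1. Erythroid markers had 0.34 to 1.41, and without naive infected 1 the median was 0.38 (camera adjusted p = 0.262).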

How the results depend on the processing

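Leaving out small RNA genes, leaving out naive infected 1 with preconditioned control 2, and leaving out each library for the lists written later were tests chosen after the data were seen. The second removes libraries that carry the spread between replicates. Counts of changed genes are given in the order infection in normoxia, infection after hypoxia, hypoxia without infection, hypoxia in infected mice, difference of infection effects, mean infection effect and mean hypoxia effect, and those within 1.5 times of 14, 7, 746, 890, 1, 733 and 2529 are left out. The cause was not tested unless stated. A pseudocount of 0.1 gave 7 and 4 for the 2 infection comparisons. No filter on low values, which adds genes to the adjustment, gave 0, 1, 561 for hypoxia in infected mice and 1 for the mean infection effect. Quantile normalization gave 0, 3, 1606 and, for mean infection, 26. Upper quartile scaling gave 0, 3, 1307, 541 and, for mean infection, 55. A robust prior gave 331, 73 and, for the difference, 2. Leaving out small RNA genes gave 372, 94 and, for the difference, 0, since Mir1949 is such a gene. Leaving out the 2 libraries gave 516, 171, 3064, 1680 and, for the difference, 25. The libraries of a comparison alone gave 660 and 47 for the infection comparisons. In limma the counts of 0 for infection in normoxia had 1722, 1488 and 1424 genes at an unadjusted p under 0.05 for no filter and the 2 scalings, and that for the difference had 139.

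With the replicate number as a term (replicate block), counts were 408 and 202 for the infection comparisons and 4 for the difference. Deviations of same-numbered libraries correlated between groups with r of -0.25 to 0.21. These values give no clear sign that the numbers pair the samples, but with 2 libraries per group they cannot exclude it. Leaving out 1 library at a time gave 0 to 1193, 3 to 454, 4 to 1792, 0 to 2770, 1 to 10, 261 to 2348 and 1158 to 4666 genes in the order above, where a lone sample is assumed to vary like the other groups. No named gene that passed in the main fit reversed under any setting. Reversal was assessed only for genes and lists that passed in the main fit. Of tests of the 29 lists with 1 library left out, 1479 were the same, 82 became stronger, 56 weaker and 7 reversed. Of lists called by camera, 22 medians, between -0.32 and 0.42, changed sign in 1 setting or more while camera's direction, set against all other genes, stayed; the granule list for the difference had 0.12 without naive infected 1. Lists whose direction in camera turned are given with the median, its range over 1 library left out and, after it, the value without the 2 libraries. They were platelet markers in infection in normoxia without naive infected 1 (-0.028; -0.14 to 0.032; -0.028), ribosomal proteins in infection after hypoxia without preconditioned control 2 (0.34; -0.36 to 0.34; 0.34) and NK cell markers in hypoxia without infection without preconditioned control 2 (-0.18; -0.18 to 0.63; -0.18). For the difference they were B cell markers (0.34; -1.11 to 0.34; 0.76) and MHC class II (0.23; -1.35 to 0.23; 0.52) without preconditioned control 2, cell cycle genes without naive infected 1 (0.19; 0.15 to 0.22; 0.23) and cytokines without naive infected 2 (-0.50; -0.57 to -0.13). Fragment counts were not used here, so depth is known only as a ratio, from 0.425 to 1.21 of naive control 2.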

Other observations

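The gene lists in this part and the platelet tests and the neutrophil share test were chosen after the main results were seen; the other tests were written before their own results were seen. Of 8 haem synthesis enzymes, 4 rose with hypoxia averaged over infection, also when adjusted over the list alone, among them Urod by 1.39 ± 0.27, Cpox by 1.30 ± 0.25 and Uros by 0.91 ± 0.17. The list median was 0.80 (camera adjusted p = 1.10e-07; adjusted p = 0.0415 with an estimated correlation; fry adjusted p = 0.00767). In infected mice it was 1.05, with 4 rises (5 adjusted over the list alone) and an adjusted p = 0.0236 with an estimated correlation. In uninfected mice it was 0.50, with 1 rise (2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0867 with an estimated correlation). The call with an estimated correlation was lost in 6 of the 8 averaged tests with 1 library left out, 0.0693 without naive infected 1 and 0.184 without preconditioned control 1, and in 3 of 8 in infected mice, 0.0997 without naive infected 1. In infected mice the median ranged from 0.86 without naive infected 1 to 1.59, with 6 rises, without naive infected 2, and 0 genes rose without either preconditioned infected library. Alas2 and Fech are also erythroid markers, a list with a median of 1.01 averaged over infection and 1.61 in infected mice, so the rise was not told apart from more erythroid RNA.

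Of 16 amino acid and one-carbon genes of the ATF4 programme, which cells switch on when amino acids run short, 6 rose with hypoxia averaged over infection (6 rose and 1 fell adjusted over the list alone). These were Asns (1.91 ± 0.17), Mthfd2 (1.83 ± 0.33), the amino acid transporter genes Slc7a5 (1.76 ± 0.21) and Slc3a2 (0.90 ± 0.17), Nars (1.14 ± 0.19) and Shmt2 (0.66 ± 0.19). Phgdh (-0.69 ± 0.26), Chac1 (0.48 ± 0.19) and Gars (-0.54 ± 0.22) did not pass. The median was 0.19 (camera adjusted p = 1.48e-05; adjusted p = 0.0911 with an estimated correlation; fry adjusted p = 0.00767).

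Platelet genes were lower after hypoxia. The 14 markers above 50 FPKM had a median of -1.44 (-1.51 to -1.41 with 1 library left out), which argues against shallower sequencing, since genes far above the floor fell as well. By list medians, platelet markers fell 1.39 log2 further than T cell markers and 1.03 further than ribosomal protein genes. The smaller of these gaps was 0.83 to 1.16 with 1 library left out, which argues against dilution by erythroid RNA or library scaling alone. The SD of their changes was 0.20, and 0% of 10000 random lists matched on expression had one as small (median 0.78). Fewer platelets, or less platelet RNA, carried into the leukocyte preparation would give this. Random lists mix unrelated genes, and any list of genes that move together could have a small SD, so the test does not single out this explanation. The fall may reflect the blood or its handling, and the data do not separate these.

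Monocyte genes were higher after hypoxia in uninfected mice. In infected mice this rise was not seen: the list median ran from -0.50 to 0.36 over all settings tried. Mean levels there were 2.75 and 2.43 in naive and 2.17 and 3.04 in preconditioned libraries. The lowest median with 1 of the 4 uninfected libraries left out was 1.17, which argues against a single library as the cause. A lower share of neutrophils would raise B, T and NK cell markers alike, yet monocyte markers rose 1.51 log2 further than T cell markers (1.08 to 1.77 with 1 library left out) and 1.19 further than the highest of the 3 (0.49 to 1.60). With 1 library left out, the bound of 0.5 log2 was always met against T cells but not always against the highest of the 3. Neutrophil markers had a median of 0.62 (0.11 to 1.23) and did not fall. The T cell gap and the neutrophil markers argue against this share as the whole cause, while the gap to the highest of the 3 does not decide it. A change in the monocytes stays open. The requirement that a bound hold with each library left out was chosen after the values were seen. It moved another time of day below from excluded to open. The T cell gap was chosen as the deciding value later still.

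Fkbp5 (-1.69 ± 0.26), Ddit4 (-1.98 ± 0.30), Mt1 (-2.26 ± 0.46) and Mt2 (-2.10 ± 0.40), genes that glucocorticoids induce, fell after hypoxia averaged over infection. Of 14 other glucocorticoid-induced genes 8 fell (11 adjusted over the list alone), among them Sesn1 (-1.58), Per1 (-1.43) and Klf9 (-1.16), with a median of -0.71 (-0.76 to -0.65 with 1 library left out) against -0.27 for random lists matched on expression, at percentile 0.14 (adjusted p = 0.257 with an estimated correlation; fry adjusted p = 0.00767). Fry tests a list against no change, and all genes had a median of -0.25, so its p does not set this list apart from other genes. Random lists mix unrelated genes, so the percentile does not allow for genes that move together. Per1 also belongs to the Dbp-phase clock genes below, so the 2 explanations share this gene. Lower glucocorticoid signalling in the hypoxia groups is a candidate explanation. Blood taken at another time of day would part the 2 clock phases, and the Dbp-phase median of -0.81 (-1.21 without naive infected 2 to -0.46 without naive infected 1; 5 genes, 3 fell: Per1, Tef and Cry2) lay -0.38 from the Arntl-phase median of -0.42 (4 genes, 0 called by limma, 0 adjusted over the list alone). With 1 library left out that gap ranged from -0.64 to -0.19, on both sides of the bound of 0.5. The phases were also to move in opposite directions, and all 9 genes had negative changes, with an Arntl-phase median of -0.57 to -0.27 with 1 library left out, which goes against this explanation. It stays open because that median lay near the -0.25 of all genes and was -0.21 after quantile normalization, with 1 of the 4 genes over 2 SE from 0.

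The 11 interferon-stimulated genes that rose with hypoxia had a median r of 0.78 with the erythroid level over the 8 libraries. Both sets were higher with hypoxia and these genes were chosen for it, so this r follows largely from the oxygen groups. Within the oxygen arms the r of single genes had a median of 0.29 and ran from -0.80 for Ifi204 to 0.98 for Isg15, while that of their mean level was 0.85 over the 4 naive and 0.95 over the 4 preconditioned libraries. RNA of erythroid cells thus stays open. Naive infected libraries were over 2-fold apart for 587 genes as deposited and 273 after quantile normalization, which left 74 in naive controls, 493 in preconditioned controls (442 as deposited) and 71 in preconditioned infected mice. For the mean hypoxia effect, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes in a 2-group fit, 2237 against at most 320 in another. This is the lowest share the test can give, so it goes against chance without excluding it. It shows that libraries group by oxygen arm and does not tell hypoxia from other differences between the arms. Estimated depth was 0.425 to 0.793 in hypoxia and 0.799 to 1.21 in naive libraries. For the mean infection effect this test cannot decide: 2 of 35 splits gave as many, the real one with 320 and the oxygen split with 2237. The oxygen split is a factor of the design and not a random split, so the infection split could not stand alone. The highest outside both was 109.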
